A study of Homo sapiens with 26 samples.

How the data were processed

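The 26 polyA RNA libraries of human embryonic stem cells were prepared with the NEBNext Ultra kit, per the labels' protocols. The values used are raw read counts per gene that the authors deposited as count tables. Per the submitters' processing notes, adapters were trimmed with cutadapt 4.1, reads checked with FastQC 0.11.9, aligned to hg38 with Bowtie2 2.4.5, sorted with SAMtools 1.6 and counted with featureCounts 2.0.1. Per the file headers, featureCounts counted fragments of paired reads, dropped chimeric pairs, counted multi-mapped reads at every place (option -M) and used no strand information. Per the file headers, set 2 was counted on UCSC refGene and sets 3 and 4 on GENCODE version 41 by gene name. The set 1 counts were deposited as 1 combined table that names no tool, and its 28278 symbols equal those of set 2 in name and order. For set 4 the file headers name an alignment folder after STAR, while the submitters' processing notes name Bowtie2. In 3 columns of the combined table IGF2BP1 is spelled with IGF1, and these were taken for the IGF2BP1 lines.

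Sets 1 to 3 were read from the library numbers in the labels, and set 4, whose rAPOBEC1 labels hold no number, from its deposited tables. Tables of sets 1 and 2 hold 28278 symbols and those of sets 3 and 4 hold 60606, of which 25872 are shared, and 98.9% of set 1 counts and 90.1% of set 3 counts lie on shared symbols. Symbols of sets 1 and 2 are summed over alternative sequences of the assembly. No pair of replicate columns was identical.

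Groups were compared with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood fits and tests with robust spread, TMM scaling and the filterByExpr filter by group. The p-values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. Sets 1 and 3 were fitted together with a set term (14 libraries, 16773 genes, 6 residual degrees of freedom, biological variation of 18.5%). Each of their lines is thus compared with the 1 control library of its set. Set 2 was fitted alone (10 libraries, 17259 genes, 5 residual degrees of freedom, 17.8%). Lines of sets 2 and 4 were set against the control with no set term. CPM were computed from the deposited counts with TMM-scaled library sizes. A fold against libraries at 0 was computed against a floor of 3 counts per library.

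The groups, the tests, the lists, the naming rule and the alternatives of normalization, test, filter, replicates, block, set term and spread were chosen before the data were examined. The naming rule took the transgenes and, per contrast, the 6 called genes with the largest and the 6 with the smallest log2 fold change, from genes with a mean of at least 5 CPM and with every library of one side above every library of the other. It also took up to 4 members of each list with a call, and at most 30 genes per contrast. Y-linked genes, XIST, pseudogenes of ribosomal and mitochondrial genes and loci named by a clone were counted but not named. The lists were tested with camera of limma 3.58.1 on log2 CPM, at a preset correlation of 0.01 and with an estimated correlation, adjusted over all lists and contrasts of a fit. There were 22 lists: pluripotency, naive or formative pluripotency, neural and ectoderm, primitive streak and mesoderm, endoderm, trophoblast and amnion, neural crest, fibroblast and stroma, blood and endothelium, interferon stimulated, p53 targets, integrated stress and unfolded protein response, cholesterol biosynthesis, glycolysis and hypoxia, mitochondrially encoded, replication dependent histones, immediate early, cytosolic ribosomal proteins, cell cycle, IGF2BP-bound mRNAs, editing enzymes and cofactors, and heat shock.

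Alternatives were DESeq2 1.42.0 (size factors, and its Wald test), no filter, each library left out in turn, the replicate number as a block, the compared sets or groups fitted alone, no set term, and the spread of all 26 libraries. Leaving out the IGF2BP1-hAPOBEC1 pair, the enzyme contrasts within IGF2BP2 and within IGF2BP3, and the mitochondrial genes of set 3 were added after the data were seen. The fits were tested on simulated counts with 200 changed genes. In the simulated IGF2BP1-ADAR comparison with the control (16773 genes) 21 of 100 genes changed by 1 on the log2 scale and 76 of 100 changed by 2 were recovered, with 10 false calls. In the simulated rAPOBEC1 against hAPOBEC1 comparison of set 2 (17259 genes) 71 and 93 were recovered, with 12 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads, editing sites and untreated cells were not used here.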

Results

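PolyA RNA of human embryonic stem cells was sequenced in 26 libraries of 13 groups, with 2 libraries per group. Each line except the control carried a tet-ON transgene, an expression cassette switched on by doxycycline, and per the labels every library came from cells given doxycycline for 24 hours, the control cells included. The transgenes encoded an RNA-editing enzyme alone (ADAR, human APOBEC1 called hAPOBEC1, or rAPOBEC1, taken here for the rat enzyme) or the same enzymes joined to an RNA-binding protein, IGF2BP1, IGF2BP2 or IGF2BP3. ADAR deaminates adenosine and APOBEC1 deaminates cytidine, so a fused editor can mark the mRNAs that its binding partner touches. Editing sites in reads were not analysed here. The gene counts ask instead how the cells' own mRNA levels differed between lines. Each transgene is in 1 group of 2 libraries, and untreated cells were not used. An effect of a transgene, enzyme or partner therefore cannot be told apart from other differences between lines. The libraries fall into 4 sets of 7, 10, 7 and 2, set 4 being rAPOBEC1. The control has 1 library in set 1 and 1 in set 3, and sets 2 and 4 hold no control. Total counts ran from 13450656 to 24816011 per library. Levels are in CPM, counts scaled to library size with TMM factors, ± gives the SD of 2 libraries unless another n is stated, and intervals and floors cover counting error only. Nothing in the labels says that replicates were separate cultures, so the p-values may measure technical spread. Genes named for their fold change had every library of one side above every library of the other.

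The transgenes were read first, since they check the labels. APOBEC1 (hg38 chromosome 12, 7649400 to 7665908), a gene of the intestine that is silent in these cells, stood at 1090 ± 20.2 CPM in hAPOBEC1 cells, 119.8 ± 98.4 in IGF2BP1-hAPOBEC1, 431.1 ± 93.3 in IGF2BP2-hAPOBEC1 and 1541 ± 69.6 in IGF2BP3-hAPOBEC1. It was at 0 counts in every other library, all rAPOBEC1 lines included, so the rAPOBEC1 transgene cannot be read from these counts. In hAPOBEC1 cells APOBEC1 was at least 6030-fold above the control of its set (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0417), taking 3 counts per library as the floor. In IGF2BP1-hAPOBEC1 it was at least 610-fold above (adjusted p = 0.0915, not called), with 189.4 CPM in replicate 1 and 50.2 in replicate 2. IGF2BP2 (chromosome 3, 185643130 to 185825042) was at 160.2 ± 32.9 CPM in the control and at 471.2 ± 10.5, 1484 ± 193 and 6778 ± 132 in IGF2BP2-ADAR, IGF2BP2-hAPOBEC1 and IGF2BP2-rAPOBEC1. IGF2BP3 (chromosome 7, 23310209 to 23470491) was at 149.3 and 293.4 CPM in the control libraries, 3896 ± 401 in IGF2BP3-hAPOBEC1, 922.1 ± 281 in IGF2BP3-rAPOBEC1 and 349.9 ± 91.3 in IGF2BP3-ADAR, where the log2 fold change of 0.67 across sets was not called (adjusted p = 0.266). Within set 2 it was at 121.1 ± 11 in IGF2BP2-hAPOBEC1 and 124.2 ± 11.5 in IGF2BP2-rAPOBEC1. IGF2BP1 was already at 532.1 ± 1.41 CPM in the control, and at 506.1 ± 63.2, 819.8 ± 371 and 647.7 ± 65.2 in IGF2BP1-ADAR, IGF2BP1-hAPOBEC1 and IGF2BP1-rAPOBEC1, none of them called. ADAR stood at 600.3 ± 27.2 CPM in the control and at 423.9 ± 14.8 in ADAR cells, 424.4 ± 70.2 in IGF2BP1-ADAR, 463.8 ± 23.1 in IGF2BP2-ADAR and 523 ± 37.9 in IGF2BP3-ADAR. A recoded cDNA or a lone catalytic domain would escape this count, so a missing rise of ADAR or IGF2BP1 checks nothing.

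**Figure D1:**
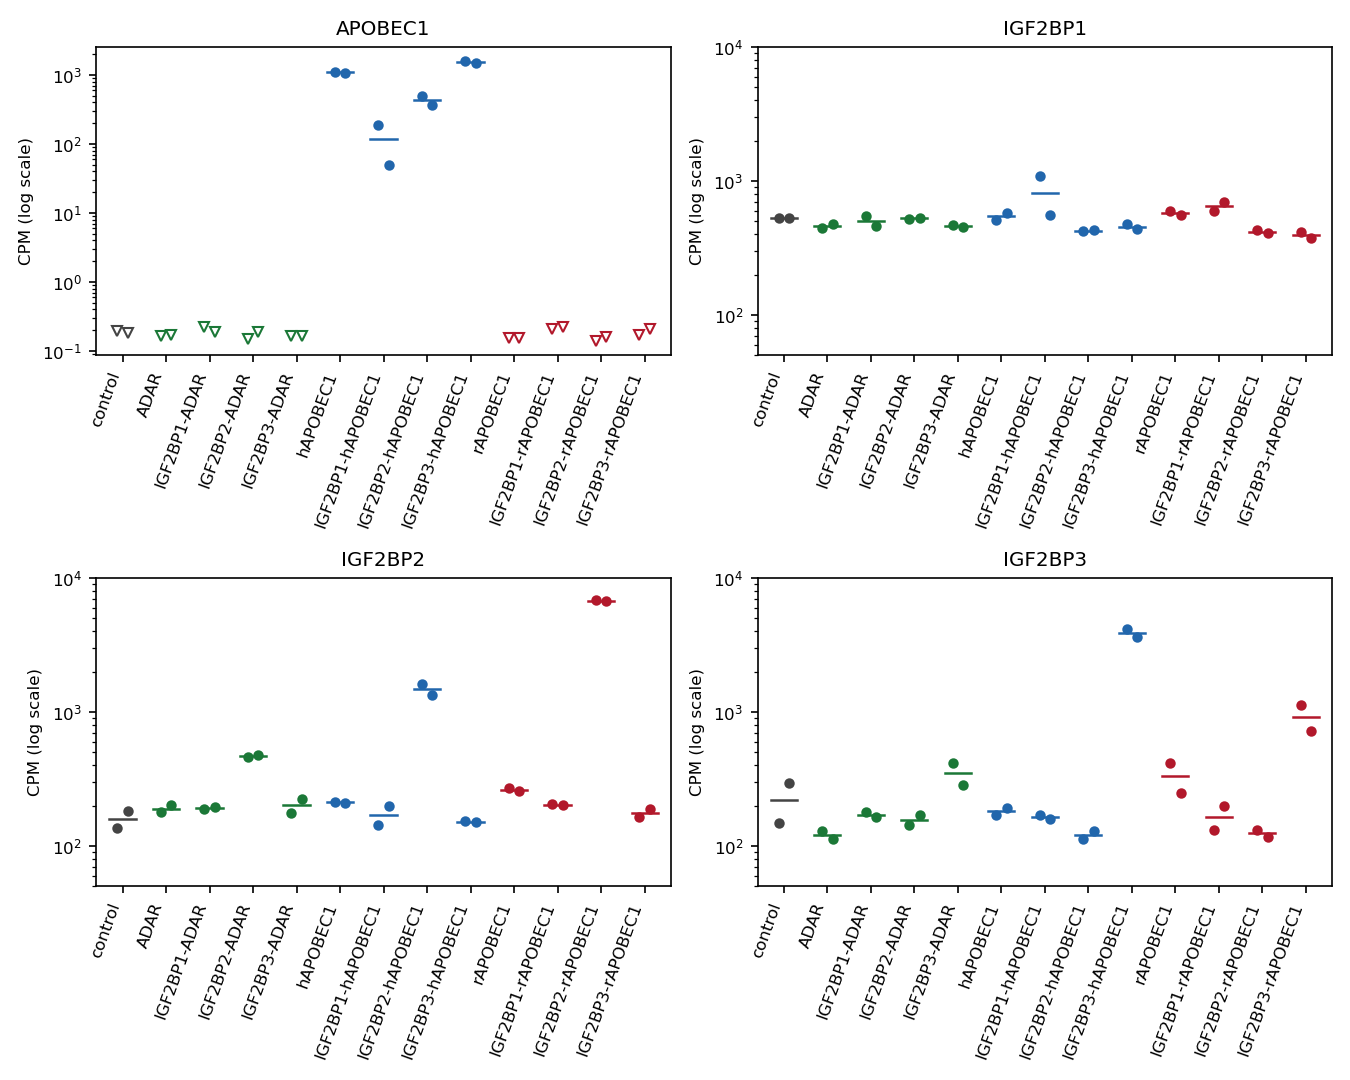
APOBEC1, IGF2BP1, IGF2BP2 and IGF2BP3 in CPM on a log axis for the 13 groups, with dots for libraries, bars for group means and open triangles for libraries at 0 counts drawn at their floor of 3 counts. APOBEC1 was read only in the 4 hAPOBEC1 lines, and IGF2BP2 reached 6778 CPM in IGF2BP2-rAPOBEC1 against 160.2 in the control.

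Lines of sets 1 and 3 were each compared with the single control library of their own set, in 1 model of 14 libraries and 16773 genes. The lone control is assumed to vary like the other groups, whose replicate pairs set the spread. That control was never left out of its own comparisons, so statements on libraries left out cover the other libraries alone. The number of genes called ran from 27 in IGF2BP1-hAPOBEC1 to 3854 in IGF2BP1-rAPOBEC1.

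**Figure D2:**
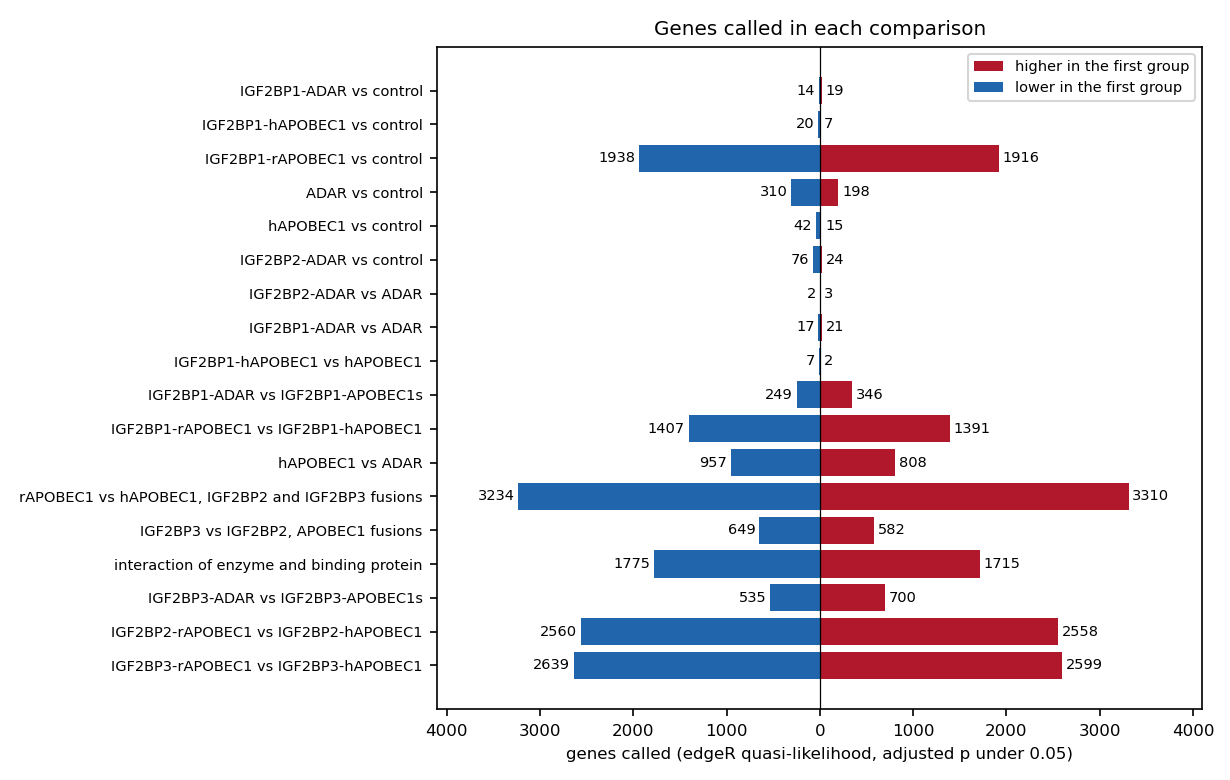
Genes called higher (red, right) and lower (blue, left) in the first group of each comparison, by edgeR quasi-likelihood at an adjusted p under 0.05. IGF2BP1-rAPOBEC1 against its control had 1916 higher and 1938 lower, and IGF2BP1-ADAR against its control 19 and 14.

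In IGF2BP1-ADAR cells 4 of 25 genes of cholesterol synthesis were called lower than in the control. INSIG1, a sterol sensor of the endoplasmic reticulum, fell by 1.54 on the log2 scale to 38.8 ± 4 CPM from 112.5 (adjusted p = 0.01) and SQLE by 1.21, and HSD17B7 was called lower as well (adjusted p = 0.0411). When adjusted over the list alone 21 were lower, with a median log2 fold change of -1.15 (camera adjusted p = 3.09e-16, adjusted p = 0.501 with an estimated correlation). Of the genes of the integrated stress and unfolded protein response, SESN2, a stress-induced sestrin, rose by 1.29 to 272.2 ± 30.9 CPM. It was the 1 member called of 30, with 9 higher when adjusted over the list alone and a median of 0.40 (adjusted p = 0.002, adjusted p = 0.828 with an estimated correlation). Replication-dependent histones, whose mRNAs lack a polyA tail and so follow the RNA selection, had no member called of 17 and a median of -1.60, or -1.61 with genes at 0 set to their bound (adjusted p = 1.66e-06, adjusted p = 0.263 with an estimated correlation). When adjusted over the list alone 7 of them were lower. The 36 cell cycle genes had none called either and a median of -0.29 (adjusted p = 0.002, adjusted p = 0.729 with an estimated correlation). Of 26 pluripotency genes 1 was called lower, 4 lower and 1 higher when adjusted over the list alone, with a median of -0.12 (adjusted p = 0.0477, adjusted p = 0.501 with an estimated correlation). The call was lost without IGF2BP1-ADAR replicate 1, ADAR replicate 1 or either library of IGF2BP1-rAPOBEC1, IGF2BP2-ADAR or hAPOBEC1. The 12 fibroblast and stroma markers had none called, 3 higher when adjusted over the list alone, and a median of 0.66 (adjusted p = 0.0264, adjusted p = 0.633 with an estimated correlation), a call lost without IGF2BP1-ADAR replicate 1 (adjusted p = 0.128). Outside the lists CSAG3, a cancer-testis antigen, stood at 16.2 ± 1.34 CPM against 0 counts, at least 81.7-fold higher. BST2, an antiviral membrane protein, rose to 90.9 ± 36.4 from 12.4 CPM, and TSC22D3, a glucocorticoid-induced gene, to 44.4 ± 16.3 from 7.13. TUBB3, the neuronal beta-tubulin, fell to 114.2 ± 45.7 from 473.9, and GDF3, a ligand of pluripotent cells, to 3.96 ± 0.247 from 13.6.

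In all 33 genes were called, 19 higher and 14 lower, of which 0 were called by edgeR when set 1 was fitted alone (1095 at an unadjusted p under 0.05, and 341 by DESeq2's Wald test in the 14 libraries). With replicates blocked 17 were called, 16 of the 33 among them, and without a set term 9, 5 of the 33 among them. The count was 903 with no filter and 73 with the spread of all 26 libraries. It was 18 without IGF2BP1-ADAR replicate 1 and 1 without replicate 2, 1532 and 1543 without IGF2BP1-hAPOBEC1 replicates 1 and 2, 5 without any library of IGF2BP2-ADAR or hAPOBEC1, 4 without either ADAR library and 1538 without the IGF2BP1-hAPOBEC1 pair. Of the 16 named calls 1 stood whichever library was left out.

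In IGF2BP1-hAPOBEC1 cells 2 of 26 markers of pluripotency were called lower than in the control. PRDM14, a repressor that guards the embryonic stem cell state, fell by 1.78 to 30.3 ± 7.04 CPM from 104.2, and GDF3 by 1.55. FOXD3 (33.4 ± 5.68 against 74.7 CPM) and the DNA methyltransferase gene DNMT3B (1302 ± 299 against 2660 CPM) were not called (adjusted p = 0.0922 and adjusted p = 0.0993). The list had 7 lower when adjusted over the list alone and a median of -0.55 (adjusted p = 1.1e-06, adjusted p = 0.222 with an estimated correlation). Cholesterol genes had a median of -0.40 (adjusted p = 0.000657, adjusted p = 0.773 with an estimated correlation), a direction that turned without a set term. Histones had none called and a median of -0.98 (adjusted p = 0.000514, adjusted p = 0.442 with an estimated correlation). The 30 p53 targets had none called and a median of -0.25 (adjusted p = 0.00777, adjusted p = 0.872 with an estimated correlation), and without IGF2BP1-hAPOBEC1 replicate 1 they turned upwards (adjusted p = 0.835). HLA-DMB, of antigen presentation, rose by 2.73, though its counts are taken to be summed over 7 alternative sequences of the assembly. GALNT16, a glycosyltransferase, rose by 2.08 and the protocadherin PCDHB5 fell by 3.08.

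The 27 genes called, 7 higher and 20 lower, fell to 0 by edgeR when set 1 was fitted alone (1111 at an unadjusted p under 0.05, and 303 by DESeq2's Wald test in the 14 libraries), with 14 called without a set term and 997 with no filter. The count was 4399 without IGF2BP1-hAPOBEC1 replicate 1 and 215 without replicate 2, 15 without either IGF2BP1-ADAR library, 7 without any library of IGF2BP2-ADAR or ADAR and 8 without either hAPOBEC1 library, while 4 of 12 named calls, ACTA1, GALNT16 and PCDHB5 among them, stood in every case.

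IGF2BP1-rAPOBEC1 cells had 3854 genes called against the control of their set, 1916 higher and 1938 lower. PEG3, an imprinted zinc finger gene at 83.5 CPM in the control, was at 0 counts in both libraries, at least 379-fold lower (adjusted p = 3.08e-05). LINC02693 and ZNF280B were also at 0, the latter at least 113-fold lower. TRPC4, a cation channel, fell by 5.69 to 1.07 ± 0.21 from 55.6 CPM, and FEZF1 and FEZF1-AS1, which lie against each other and cannot be separated without strand information, fell by 5.84 and 5.37. Genes barely seen in the control came up: CR1L at 12.4 ± 7.38 CPM and DNAJC15 at 11.8 ± 1.27 were at least 62.5-fold and at least 59.3-fold above 0 counts. CTCFL, a germline relative of CTCF, was at 19.5 ± 14.3 CPM against 2 counts, a ratio with a counting interval of 40 to 1200, and FGF18 against 1 count had an interval of 32.5 to 7230. Of 30 stress-response genes 11 were called higher and 1 lower, 12 and 1 when adjusted over the list alone, with a median of 0.76 (adjusted p = 0.00762, adjusted p = 0.841 with an estimated correlation). The list call was lost without IGF2BP1-rAPOBEC1 replicate 1. Among these genes DDIT3 rose by 2.80 to 23.5 ± 3.85 CPM, VLDLR by 2.24, TRIB3 by 1.86 and ATF3 by 1.72. The p53 targets had 6 called higher, also 6 when adjusted over the list alone, and a median of 0.55 (adjusted p = 0.0342, adjusted p = 0.887 with an estimated correlation), a call lost without IGF2BP1-rAPOBEC1 replicate 1 (adjusted p = 0.255). Cholesterol genes had 13 called lower, 17 lower and 1 higher when adjusted over the list alone, and a median of -0.79 (adjusted p = 0.000108, adjusted p = 0.693 with an estimated correlation). HMGCS1, an enzyme of the mevalonate pathway, fell by 1.67 and LSS by 1.46. Histones had 6 called lower, 7 when adjusted over the list alone, and a median of -1.75 (adjusted p = 0.000554, adjusted p = 0.442 with an estimated correlation), and H2BC9 fell by 2.35. Cell cycle genes had 14 lower and 4 higher, 16 and 5 when adjusted over the list alone, with a median of -0.37 (adjusted p = 0.033, adjusted p = 0.828 with an estimated correlation, and adjusted p = 0.126 without IGF2BP1-rAPOBEC1 replicate 2). The count of genes was 564 when set 1 was fitted alone, 2116 without a set term and 6680 without the IGF2BP1-hAPOBEC1 pair. It was 2095 and 2526 without IGF2BP1-rAPOBEC1 replicates 1 and 2 and 6671 and 6703 without IGF2BP1-hAPOBEC1 replicates 1 and 2, and 20 of 24 named calls stood whichever library was left out.

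ADAR cells carried transcripts of the primitive streak, the first step out of pluripotency. The streak list was called higher in hAPOBEC1 and IGF2BP2-ADAR too, against the same control library, whose own state may add to it. EOMES was at 9.26 ± 5.72 CPM and FGF17 at 8.04 ± 3.21 against 0 counts, at least 50.9-fold and at least 44.2-fold higher, and CER1, a Nodal antagonist, rose by 5.27 to 26 ± 8.75 from 0.666 CPM. TBXT, the brachyury gene, stood at 5.33 ± 2.88 CPM against 1 count, a ratio with a counting interval of 15.5 to 3460. Of 17 streak and mesoderm genes 5 were called higher, 9 when adjusted over the list alone, and the median was 2.83, the same with genes at 0 set to their bound (adjusted p = 0.000236, adjusted p = 0.501 with an estimated correlation). The endoderm factor FOXA2 was at 13.4 ± 8.2 CPM against 0 counts, at least 73.9-fold higher, and 2 of 12 endoderm genes were called higher (adjusted p = 0.0639 for the list). NPTX1, a neuronal pentraxin, fell by 7.47, SOX21 fell by 5.48, POU3F4 fell by 4.69 and IRX2 fell by 4.26. Stress-response genes had 7 of 30 called higher, 15 when adjusted over the list alone, and a median of 0.96, or 0.93 with the gene at 0 set to its bound (adjusted p = 3.38e-07, adjusted p = 0.633 with an estimated correlation). CHAC1 rose by 2.38 to 70.4 ± 1.08 from 13.5 CPM, DDIT3 by 2.63 and XBP1 by 1.14. Of 30 glycolysis and hypoxia genes 5 were called lower, 6 when adjusted over the list alone, with a median of -0.25 (adjusted p = 0.002, adjusted p = 0.779 with an estimated correlation), and ALDOA fell by 2.09, EGLN3 by 1.62 and ADM by 1.40. The 55 ribosomal protein genes had RPL26 and RPS21 called higher by 1.61 and 1.22, 4 higher when adjusted over the list alone, and a median of 0.32 (adjusted p = 7.38e-05, adjusted p = 0.887 with an estimated correlation). Their reads are shared with pseudogenes and were counted at every place they mapped, and RPL26 turned to -1.16 without a set term. Interferon-stimulated genes had 1 of 25 called and a median of 0.41 (adjusted p = 0.0457, adjusted p = 0.633 with an estimated correlation), and lost the call without ADAR replicate 2 (adjusted p = 0.0851), IGF2BP1-hAPOBEC1 replicate 1 or 2 (adjusted p = 0.0768 and adjusted p = 0.0704) or control replicate 1 (adjusted p = 0.0576). IGF2BP3 fell by 1.25 (adjusted p = 0.0136) to 121.8 ± 11.5 from 293.4 CPM in the set 3 control, though the set 1 control held 149.3 and the other lines of set 3 144.5 to 192.

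ADAR cells had 508 genes called, 198 higher and 310 lower, 4931 when set 3 was fitted alone, 1086 by DESeq2's Wald test and 2493 without the IGF2BP1-hAPOBEC1 pair. They were 948 without a set term, 1398 with no filter and 767 with the spread of all 26 libraries. The count was 55 and 16 without ADAR replicates 1 and 2, 2457 and 2488 without IGF2BP1-hAPOBEC1 replicates 1 and 2, 268 and 271 without IGF2BP2-ADAR replicates 1 and 2 and 277 without either hAPOBEC1 library, and 2 of 23 named calls, ABCA17P and PPIAP46, stood in every case.

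In hAPOBEC1 cells 1 of 17 streak and mesoderm genes was called higher. CER1 rose by 4.48 to 15.0 ± 1.25 CPM, and POU3F4 fell by 4.45, while EOMES (4.13 ± 1.5 CPM against 0 counts, at least 22.7-fold), TBXT (3.03 ± 0.145 CPM against 1 count, a ratio with an interval of 8.77 to 1990) and FOXA2 (3.16 ± 0.93 CPM, at least 17.4-fold) were not called (adjusted p = 0.0666, adjusted p = 0.0663 and adjusted p = 0.0759). The list had 7 higher when adjusted over the list alone and a median of 1.43, with or without bounds (adjusted p = 0.000385, adjusted p = 0.501 with an estimated correlation). The 12 endoderm genes had none called, 2 higher when adjusted over the list alone, and a median of 0.77, with or without bounds (adjusted p = 0.00837, adjusted p = 0.501 with an estimated correlation). Cholesterol genes leaned upwards with none called, 5 higher when adjusted over the list alone and a median of 0.36 (adjusted p = 0.0101, adjusted p = 0.828 with an estimated correlation), a direction that turned without a set term. SLC39A8, a zinc and manganese carrier, rose by 2.30 to 127.6 ± 2.11 CPM, HAS2, which makes hyaluronan, by 2.22 and tenascin C (TNC) by 1.68, while FEZ1 fell by 2.35 and DHRS3, a retinal reductase, by 2.13. Of 57 genes called, 15 higher and 42 lower, the count was 0 by edgeR without hAPOBEC1 replicate 1 (1723 at an unadjusted p under 0.05, and 356 by DESeq2's Wald test with all libraries) and 1 without replicate 2. It was 987 and 1014 without IGF2BP1-hAPOBEC1 replicates 1 and 2, 117 and 118 without IGF2BP1-rAPOBEC1 replicates 1 and 2, 28 without either IGF2BP2-ADAR library, 27 without either ADAR library, 1025 without the IGF2BP1-hAPOBEC1 pair, 627 without a set term, 613 with no filter and 3557 when set 3 was fitted alone, so that 0 of 12 named calls stood in every case.

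In IGF2BP2-ADAR cells 2 of 30 glycolysis and hypoxia genes were called lower than in the control. ALDOA fell by 2.73 to 4.66 ± 1.39 from 30.8 CPM and LDHA, lactate dehydrogenase A, by 1.05 to 642.3 ± 79.9 CPM, while PFKFB3 at -1.04 was not called (adjusted p = 0.0521). The list had 8 lower when adjusted over the list alone, with a median of -0.58 (adjusted p = 2.67e-08, adjusted p = 0.627 with an estimated correlation). Stress-response genes had none called, 11 higher and 1 lower when adjusted over the list alone, and a median of 0.59, or 0.50 with bounds (adjusted p = 4.79e-05, adjusted p = 0.729 with an estimated correlation). Streak and mesoderm genes had none called, 4 higher when adjusted over the list alone, and a median of 0.71 with or without bounds (adjusted p = 0.0106, adjusted p = 0.633 with an estimated correlation). LEFTY1, a Nodal antagonist of stem cells, rose by 2.54 to 46.9 ± 5.71 CPM, PKIB, an inhibitor of protein kinase A, by 2.74, and ANXA3 by 1.96. The bombesin receptor gene GRPR fell by 2.84, POU3F4 by 3.73 and TRPC4 by 2.81. RPL26 was called at 1.45 and turned to -1.32 without a set term. The 100 genes called, 24 higher and 76 lower, became 3392 when set 3 was fitted alone, 442 by DESeq2's Wald test, 160 without a set term, 728 with no filter and 1143 without the IGF2BP1-hAPOBEC1 pair. The count was 1 without either IGF2BP2-ADAR library, 1118 and 1150 without IGF2BP1-hAPOBEC1 replicates 1 and 2, 36 without either hAPOBEC1 library and 37 without either ADAR library, and PKIB alone of 15 named calls stood in every case.

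The annotation of set 1 does not hold the mitochondrial genes, so the 15 mitochondrially encoded genes were tested in set 3 alone, on 20868 genes, a test chosen after the data were seen. All 3 lines were set against the same single control library. Of the 15 genes those called higher were 11 in ADAR cells with a median of 0.83 (camera p = 2.81e-07, p = 0.0436 with an estimated correlation), 15 in hAPOBEC1 with a median of 0.80 (p = 4.69e-11, p = 0.023 with an estimated correlation) and 11 in IGF2BP2-ADAR with 1 lower and a median of 0.85 (p = 3.24e-08, p = 0.0362 with an estimated correlation). They took 4.83% of counts in the single control library and 7.13% to 7.45% in the 6 libraries of the lines. In the rAPOBEC1 libraries of set 4 they took 7.46% and 7.39%, so among the 9 libraries with these genes the control stood apart.

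Lines that share a control library correlate by that alone, so each correlation of log2 fold changes across genes was set beside its value in 20 simulations with unchanged groups. Genes are not independent replicates. ADAR and IGF2BP2-ADAR were the pair of set 3 most alike, at 0.838 against 0.671 simulated (covariance 0.354 against 0.14). They had 22 genes called higher in both, where unchanged groups with the shared control gave 0.1 and independent lists give 0.283. They had 67 called lower in both, against 0.05 and 1.40, and 0 opposite. Neither value holds both the effects and the shared control, so part of these overlaps can come from that 1 library. Across sets, with separate controls, IGF2BP1-rAPOBEC1 and ADAR had a correlation of 0.177 against 0.004 simulated, with 57 genes higher in both, where independent lists give 22.6, 79 lower in both against 35.8, and 50 opposite. IGF2BP1-hAPOBEC1 and hAPOBEC1 correlated at 0.211 against 0.001 simulated, with 0 genes called in the same direction in both.

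Whether the binding partner adds to the enzyme was asked by setting each fusion against its enzyme alone. Within set 3, IGF2BP2-ADAR differed from ADAR in 5 genes, 3 higher and 2 lower. IGF2BP2 itself rose by 1.31, CHCHD2, a mitochondrial protein, rose by 2.23 to 64.7 ± 0.00173 from 13.8 ± 0.783 CPM, and NPFFR2, named after its value was seen, rose by 4.29. ABCA17P, a pseudogene, fell by 5.52 to 0.511 ± 0.0107 from 23.8 ± 1.99 CPM, and MAPRE1, a microtubule plus-end protein, fell by 2.23 to 218.5 ± 1.19 from 1026 ± 62 CPM. Against the control of the set CHCHD2 was lower by 3.105 and MAPRE1 higher by 2.39 in ADAR cells (adjusted p = 0.00115 for each), and neither was called in IGF2BP2-ADAR (adjusted p = 0.193 and adjusted p = 0.828). Streak and mesoderm genes had none called, 7 lower when adjusted over the list alone and a median of -1.12 (adjusted p = 7.38e-05, adjusted p = 0.501 with an estimated correlation). Endoderm genes had none called, 3 lower when adjusted over the list alone and a median of -0.98 (adjusted p = 6.08e-06, adjusted p = 0.263 with an estimated correlation), with FOXA2 at 2.14 ± 0.181 against 13.4 ± 8.2 CPM. The p53 targets had none called and a median of -0.42 (adjusted p = 2.1e-06, adjusted p = 0.666 with an estimated correlation). Stress-response genes had none called, 1 lower when adjusted over the list alone, and a median of -0.27 (adjusted p = 0.000467, adjusted p = 0.773 with an estimated correlation). Glycolysis genes had none called and a median of -0.32 (adjusted p = 0.00117, adjusted p = 0.773 with an estimated correlation). Ribosomal protein genes had none called and a median of -0.17, with 55 of 55 below 0 (adjusted p = 0.000107, adjusted p = 0.887 with an estimated correlation). Immediate early genes, which also answer handling, had none called, 1 lower when adjusted over the list alone, and a median of -0.30 (adjusted p = 0.0246, adjusted p = 0.696 with an estimated correlation). Their call was lost without ADAR replicate 2 or IGF2BP2-ADAR replicate 2. Histones had none called and a median of 0.30 (adjusted p = 0.0345, adjusted p = 0.606 with an estimated correlation). They lost the call without ADAR replicate 1 or IGF2BP2-ADAR replicate 1 or 2. The same held for IGF2BP1-hAPOBEC1 replicate 1 or 2 or IGF2BP1-rAPOBEC1 replicate 1 or 2. The count was 862 when the set's libraries were fitted alone, 87 with no filter, 24 by DESeq2's Wald test and 47 without the IGF2BP1-hAPOBEC1 pair. It was 3 without either IGF2BP2-ADAR library, 2 without either ADAR library and 45 and 48 without IGF2BP1-hAPOBEC1 replicates 1 and 2, and ABCA17P and MAPRE1 stood in every case.

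For IGF2BP1 the fusion and the enzyme alone lie in different sets, so each was first taken relative to its own control. In IGF2BP1-ADAR against ADAR 3 of 25 cholesterol genes were called lower, of which INSIG1 fell by 1.84 and HSD17B7 fell by 1.66. There were 21 lower when adjusted over the list alone, with a median of -1.42 (adjusted p = 1.81e-13, adjusted p = 0.501 with an estimated correlation, and adjusted p = 0.0762 without a set term). Streak and mesoderm genes had none called, 2 lower when adjusted over the list alone, and a median of -1.34, or -2.21 with bounds (adjusted p = 0.002, adjusted p = 0.606 with an estimated correlation). Histones had none called, 2 lower when adjusted over the list alone, and a median of -1.71 with or without bounds (adjusted p = 0.00631, adjusted p = 0.501 with an estimated correlation, and adjusted p = 0.0568 without IGF2BP1-ADAR replicate 1). The 38 genes called, 21 higher and 17 lower, include the rises of GRPR by 3.54, GADD45G by 3.46 and SYN3 by 3.00 and the falls of GDF3 by 3.34, MAPRE1 by 2.52 and CSRP1 by 2.38. CHCHD2 rose by 3.07. CHCHD2 and MAPRE1 were also called in IGF2BP2-ADAR and in hAPOBEC1 against ADAR, comparisons that share the ADAR libraries, so the ADAR line stood apart in them. The count was 1072 when the groups were fitted alone, 671 with no filter, 327 by DESeq2's Wald test, 2323 without a set term, 13 with replicates blocked and 1175 without the IGF2BP1-hAPOBEC1 pair. It was 0 by edgeR without IGF2BP1-ADAR replicate 1 or 2 or ADAR replicate 2 (1998, 2050 and 1633 at an unadjusted p under 0.05), 2 without ADAR replicate 1, 1169 and 1204 without IGF2BP1-hAPOBEC1 replicates 1 and 2, 84 and 83 without IGF2BP1-rAPOBEC1 replicates 1 and 2, 9 without either IGF2BP2-ADAR library and 5 without either hAPOBEC1 library.

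In IGF2BP1-hAPOBEC1 against hAPOBEC1 GDF3 was the 1 gene of 26 pluripotency markers called, lower by 2.83. The list had 5 lower when adjusted over the list alone, with a median of -0.35 (adjusted p = 0.000569, adjusted p = 0.263 with an estimated correlation). Cholesterol genes had none called, 1 lower when adjusted over the list alone, and a median of -0.75 (adjusted p = 2.45e-07, adjusted p = 0.633 with an estimated correlation), a direction that turned without a set term. NR5A2, a nuclear receptor that can drive POU5F1, fell by 2.97, SLC39A8 by 3.06 and TRDN by 3.14, and FIGNL2 rose by 2.75. The 14 neural genes had none called and a median of 1.50, or 1.13 with bounds (adjusted p = 0.00777, adjusted p = 0.501 with an estimated correlation, and adjusted p = 0.0519 without IGF2BP1-hAPOBEC1 replicate 1). Streak and mesoderm genes had none called and a median of -0.95, or -1.44 with bounds (adjusted p = 0.000534, adjusted p = 0.501 with an estimated correlation, and adjusted p = 0.135 without IGF2BP1-hAPOBEC1 replicate 1). The p53 targets had none called and a median of -0.29 (adjusted p = 0.00745, adjusted p = 0.869 with an estimated correlation, and adjusted p = 0.982 without IGF2BP1-hAPOBEC1 replicate 1). Cell cycle genes had none called and a median of -0.17 (adjusted p = 0.0342, adjusted p = 0.828 with an estimated correlation), a call lost without IGF2BP1-hAPOBEC1 replicate 2 (adjusted p = 0.605) or hAPOBEC1 replicate 1 (adjusted p = 0.0553). The 9 genes called, 2 higher and 7 lower, were 0 by edgeR when the groups were fitted alone (563 at an unadjusted p under 0.05), 48 higher and 56 lower by DESeq2's Wald test, 387 with no filter and 3339 without a set term. By edgeR the count was 0 without IGF2BP2-ADAR replicate 1 or 2 (1172 and 1171 at an unadjusted p under 0.05) or hAPOBEC1 replicate 1 or 2 (1055 and 1047), 4 without either ADAR library, and 2336 and 119 without IGF2BP1-hAPOBEC1 replicates 1 and 2, and 0 of 7 named calls stood in every case.

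The enzymes were compared on the same partner within set 1. IGF2BP1-ADAR against the mean of both IGF2BP1-APOBEC1 fusions (n = 4) had 595 genes called, 346 higher and 249 lower. EGR1 rose by 2.48 to 56.8 ± 11.1 from 10.2 ± 6.53 CPM and FOS by 3.05. The list of immediate early genes, which answer growth signals and handling, was not called, with 3 of 20 higher (adjusted p = 0.101). CSAG3 was at 16.2 ± 1.34 against 0.0709 ± 0.142 CPM. LEFTY1 rose by 2.20 and CHAC1 by 1.62, while PIWIL2, a germline small RNA partner, fell by 3.42, PCDHGA10 by 3.66 and RAC2 by 2.13. Cholesterol genes had 8 called lower, 14 when adjusted over the list alone, with a median of -0.56 (adjusted p = 6.36e-07, adjusted p = 0.633 with an estimated correlation), and INSIG1 fell by 1.15 to 38.8 ± 4 from 86.3 ± 13.1 CPM. Ribosomal protein genes had none called, 50 of 55 above 0 and a median of 0.18 (adjusted p = 0.000569, adjusted p = 0.92 with an estimated correlation), a call lost without IGF2BP1-ADAR replicate 2 (adjusted p = 0.739) or IGF2BP1-hAPOBEC1 replicate 2 (adjusted p = 0.198). Stress-response genes had 5 of 30 higher, 9 higher and 2 lower when adjusted over the list alone, and a median of 0.18 (adjusted p = 0.0338, adjusted p = 0.887 with an estimated correlation). Their call was lost without replicate 2 of IGF2BP1-ADAR, IGF2BP1-hAPOBEC1 or IGF2BP1-rAPOBEC1. The count was 18 when set 1 was fitted alone, 1544 with no filter, 1104 by DESeq2's Wald test and 100 without a set term. It was 98 and 95 without IGF2BP1-ADAR replicates 1 and 2, 3637 and 1910 without IGF2BP1-hAPOBEC1 replicates 1 and 2, 251 without IGF2BP1-rAPOBEC1 replicate 1, 287 without either IGF2BP2-ADAR library, 342 without either hAPOBEC1 library and 303 and 307 without ADAR replicates 1 and 2.

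IGF2BP1-rAPOBEC1 against IGF2BP1-hAPOBEC1 had 2798 genes called, 1391 higher and 1407 lower. Of 30 p53 targets 13 were called higher and 0 lower, 18 higher when adjusted over the list alone, with a median of 0.77 (adjusted p = 2.99e-07, adjusted p = 0.635 with an estimated correlation). ZMAT3 rose by 1.58 to 80.6 ± 17.9 from 27.0 ± 12.8 CPM, PLK2 by 1.39, and RRM2B was at 210.6 ± 2.9 against 91.8 ± 33 CPM. Stress-response genes had 11 higher and 0 lower, 14 higher when adjusted over the list alone, with a median of 0.66 (adjusted p = 3.38e-07, adjusted p = 0.633 with an estimated correlation), DDIT3 rising by 2.66 and STC2 by 1.54. Of 8 naive pluripotency genes 3 were called higher, also 3 when adjusted over the list alone, with a median of 0.87 (adjusted p = 0.00832, adjusted p = 0.627 with an estimated correlation). Among them TFAP2C rose by 2.35, TFCP2L1 by 0.77 and NLRP7, taken to be counted over 9 alternative sequences, by 6.12. The list lost its call without IGF2BP1-hAPOBEC1 replicate 1 or IGF2BP1-rAPOBEC1 replicate 1. The 10 neural crest genes had none called and a median of 0.81 (adjusted p = 0.0345, adjusted p = 0.501 with an estimated correlation), a call lost without IGF2BP1-hAPOBEC1 replicate 1 (adjusted p = 0.114) or IGF2BP1-rAPOBEC1 replicate 2 (adjusted p = 0.102). The chemokine CXCL5 rose by 7.10, GDA, guanine deaminase, to 21.9 ± 3.55 CPM against 3 counts, a ratio with an interval of 98.1 to 1400, and PKLR was at least 99.7-fold higher. PEG3, LINC02693, ZNF280B and LYNX1 were at 0 counts in IGF2BP1-rAPOBEC1, with PEG3 at least 296-fold, ZNF280B 114-fold and LYNX1 111-fold lower. The count was 609 when set 1 was fitted alone, 1379 without a set term, 6391 without IGF2BP1-hAPOBEC1 replicate 2 and 1254 and 1757 without IGF2BP1-rAPOBEC1 replicates 1 and 2, and 21 of 24 named calls stood whichever library was left out.

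Within set 3, hAPOBEC1 against ADAR had 1765 genes called, 808 higher and 957 lower. Of 30 stress-response genes 14 were called lower, 18 when adjusted over the list alone, with a median of -0.80, or -0.76 with bounds (adjusted p = 7.17e-07, adjusted p = 0.635 with an estimated correlation). CHAC1 fell by 2.69 to 10.95 ± 2.06 from 70.4 ± 1.08 CPM, DDIT3 by 2.01 and SESN2 by 1.39. Ribosomal protein genes had 17 of 55 called lower, 29 lower and 1 higher when adjusted over the list alone, and a median of -0.47 (adjusted p = 1.14e-09, adjusted p = 0.806 with an estimated correlation), RPS21 falling by 1.53 and RPL26 by 1.40, with reads shared with pseudogenes. Glycolysis genes had 5 called higher, 7 when adjusted over the list alone, and a median of 0.40 (adjusted p = 0.00772, adjusted p = 0.828 with an estimated correlation, and adjusted p = 0.0808 without ADAR replicate 1), with hexokinase 2 (HK2) rising by 0.93. CHCHD2 rose by 3.30 to 135.3 ± 17.7 CPM, SORBS2 by 2.16 and the NF-kappa-B subunit REL by 2.14, while PCDHB5 fell by 4.61 and CHRD, a BMP antagonist, by 2.74. The count was 7055 when set 3 was fitted alone, 2707 with no filter, 114 without a set term and 4702 without the IGF2BP1-hAPOBEC1 pair. Without either IGF2BP1-hAPOBEC1 library the count moved upwards too. It was 183 and 24 without hAPOBEC1 replicates 1 and 2, 162 and 29 without ADAR replicates 1 and 2 and 831 without either IGF2BP2-ADAR library. Of 25 named calls 8 stood in every case.

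Set 2, with 10 libraries and 17259 genes tested, holds IGF2BP2 and IGF2BP3 each with human and rat APOBEC1. With rAPOBEC1 the level of IGF2BP2 was higher than with hAPOBEC1 (6778 against 1484 CPM) and that of IGF2BP3 lower (922.1 against 3896). The level of the fusion therefore cannot be told apart from the interaction, nor from the enzyme within 1 partner. Averaged over both partners (n = 4 per enzyme), rAPOBEC1 fusions differed from hAPOBEC1 fusions in 6544 genes, 3310 higher and 3234 lower. Cholesterol genes fell almost as a block: 22 of 25 were called lower, also 22 when adjusted over the list alone, with a median of -1.06 (adjusted p = 1.36e-09, adjusted p = 0.785 with an estimated correlation). ACAT2 fell by 1.75 to 93.1 ± 19.7 from 346 ± 182 CPM, MVD by 1.80, LSS by 1.70 and NSDHL by 1.56. Stress-response genes had 17 of 29 lower and 4 higher, with the same numbers when adjusted over the list alone, and a median of -0.42 (adjusted p = 0.00465, adjusted p = 0.895 with an estimated correlation). The cystine carrier SLC7A11 fell by 2.93, the amino acid carrier SLC7A5 by 2.54 and TRIB3 by 2.23, while VLDLR rose by 1.61. HMOX1, heme oxygenase, fell by 2.97. TXNIP, which restrains glucose uptake, rose by 5.05 to 318.1 ± 32.8 from 14.9 ± 13.4 CPM, and the circadian factor gene BHLHE41 rose by 4.35. The 20 histones had 4 called lower, 3 when adjusted over the list alone, with a median of -0.50 (adjusted p = 0.0183, adjusted p = 0.785 with an estimated correlation, and adjusted p = 0.0643 without IGF2BP3-rAPOBEC1 replicate 1). Of 8 trophoblast and amnion genes 3 were called higher, 4 when adjusted over the list alone, with a median of 1.03 (adjusted p = 0.0266, adjusted p = 0.785 with an estimated correlation), a call lost without IGF2BP3-ADAR replicate 1 or 2 (adjusted p = 0.0505 and adjusted p = 0.0613) or IGF2BP3-rAPOBEC1 replicate 2 (adjusted p = 0.0751). The count was 4167 without IGF2BP2-hAPOBEC1 replicate 1 and 3970 without IGF2BP2-rAPOBEC1 replicate 1, and 24 of 27 named calls stood whichever library was left out.

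**Figure D3:**
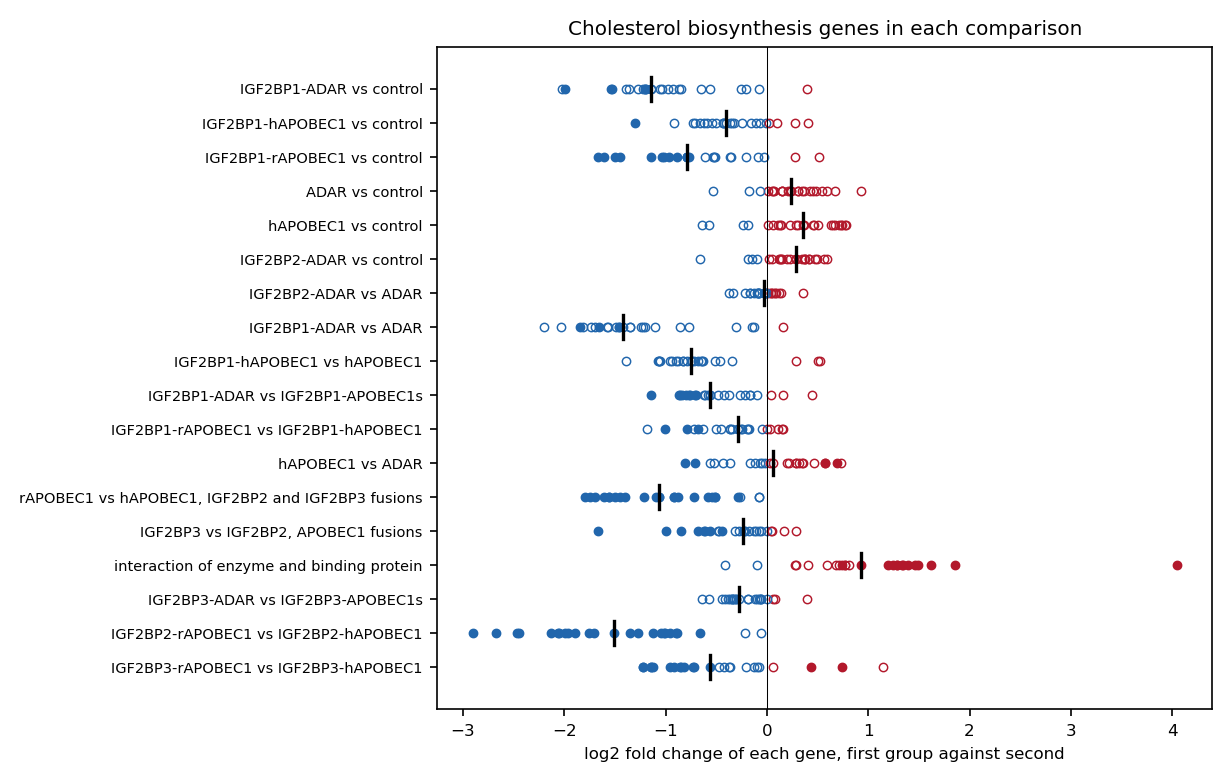
Log2 fold change of each of the 25 cholesterol biosynthesis genes in each comparison, first group against second, with filled circles for genes called, open circles for genes not called, red above 0, blue below 0 and a black tick at the median. The median was -1.51 in IGF2BP2-rAPOBEC1 against IGF2BP2-hAPOBEC1, -1.15 in IGF2BP1-ADAR against its control and 0.36 in hAPOBEC1 against its control, a direction that turned without a set term.

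IGF2BP3 fusions against IGF2BP2 fusions, averaged over both APOBEC1 enzymes (n = 4 per partner), had 1231 genes called, 582 higher and 649 lower. Of 21 immediate early genes 9 were called lower and 2 higher, 10 and 3 when adjusted over the list alone, with a median of -0.57 (adjusted p = 0.000217, adjusted p = 0.785 with an estimated correlation). EGR1 fell by 2.53, FOSB by 2.32, FOS by 2.24 while IER3, counted over 5 alternative sequences, fell by 1.18. CCN1, a target of the Hippo pathway, fell by 2.32. Vimentin (VIM), the intermediate filament of mesenchymal cells, rose by 2.34 to 480.8 ± 391 from 73.5 ± 34.3 CPM, and the netrin receptor gene UNC5C by 2.07. Histones had none called and a median of -0.55 (adjusted p = 0.02, adjusted p = 0.785 with an estimated correlation, and adjusted p = 0.0518 without IGF2BP2-hAPOBEC1 replicate 1). Cholesterol genes had 7 lower, 10 lower and 1 higher when adjusted over the list alone, with a median of -0.24 (adjusted p = 0.00446, adjusted p = 0.895 with an estimated correlation). The count was 3016 when the groups were fitted alone and 1919 by DESeq2's Wald test. It was 268 and 576 without IGF2BP2-hAPOBEC1 replicates 1 and 2, 318 and 294 without IGF2BP2-rAPOBEC1 replicates 1 and 2, 2972 and 2985 without IGF2BP3-ADAR replicates 1 and 2, 312 and 381 without IGF2BP3-hAPOBEC1 replicates 1 and 2 and 624 and 1917 without IGF2BP3-rAPOBEC1 replicates 1 and 2. Of 19 named calls 12 stood in every case.

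By the interaction test, rAPOBEC1 against hAPOBEC1 differed between the partners in 3490 genes, with 1715 effects higher in IGF2BP3 and 1775 lower. Of the p53 targets, 23 of 30 higher and 0 lower, 25 higher when adjusted over the list alone, with a median of 1.51 (adjusted p = 1.13e-08, adjusted p = 0.805 with an estimated correlation). Pluripotency genes had 17 of 26 higher and 1 lower, 19 and 2 when adjusted over the list alone, with a median of 1.47 (adjusted p = 1.77e-06, adjusted p = 0.785 with an estimated correlation), TDGF1 at 2.82, CD9 at 2.58 and DNMT3B at 2.02. Cholesterol genes had 14 higher and 0 lower, 17 higher when adjusted over the list alone, with a median of 0.93 (adjusted p = 2.07e-05, adjusted p = 0.839 with an estimated correlation). Immediate early genes had 10 lower and 2 higher, 12 and 3 when adjusted over the list alone, with a median of -1.07 (adjusted p = 0.00671, adjusted p = 0.805 with an estimated correlation). Histones had 2 of 20 lower, 1 when adjusted over the list alone, with a median of -1.32 (adjusted p = 0.00364, adjusted p = 0.785 with an estimated correlation). The count was 5473 when the 4 groups were fitted alone, 1884 and 1973 without IGF2BP2-hAPOBEC1 replicates 1 and 2, 1895 and 1617 without IGF2BP2-rAPOBEC1 replicates 1 and 2, 5461 and 5469 without IGF2BP3-ADAR replicates 1 and 2 and 1678 without IGF2BP3-hAPOBEC1 replicate 2. Of 26 named calls 25 stood whichever library was left out.

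The enzyme was then compared within each partner, a pair of contrasts chosen after the interaction was seen. With IGF2BP2, rAPOBEC1 against hAPOBEC1 had 5118 genes called, 2558 higher and 2560 lower. Cholesterol genes fell in 23 of 25 cases, also 23 when adjusted over the list alone, with a median of -1.51 (adjusted p = 8.28e-12, adjusted p = 0.785 with an estimated correlation), ACAT2 by 2.68 to 78.6 ± 0.0744 from 501.8 ± 42.9 CPM. Pluripotency genes had 14 lower and 1 higher, 15 and 1 when adjusted over the list alone, with a median of -0.93 (adjusted p = 0.000118, adjusted p = 0.805 with an estimated correlation). NODAL fell by 3.18, DNMT3B by 2.21 and ZFP42 by 1.82, and LINC-ROR, a noncoding RNA of pluripotent cells, by 6.89. The p53 targets had 12 lower, 17 when adjusted over the list alone, with a median of -0.57 (adjusted p = 0.00121, adjusted p = 0.895 with an estimated correlation), MDM2 falling by 1.78. HMX3, FOXC1 and ISLR2, genes of neural and neural crest development, rose by 7.06, 6.10 and 5.44. The count was 9047 when the 2 groups were fitted alone, 1621 and 2543 without IGF2BP2-hAPOBEC1 replicates 1 and 2 and 1740 and 1976 without IGF2BP2-rAPOBEC1 replicates 1 and 2.

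With IGF2BP3, rAPOBEC1 against hAPOBEC1 had 5238 genes called, 2599 higher and 2639 lower. The p53 targets had 18 higher and 1 lower, 19 and 1 when adjusted over the list alone, with a median of 1.02 (adjusted p = 5.87e-05, adjusted p = 0.895 with an estimated correlation). ZMAT3 rose by 2.28 to 98.8 ± 47 from 20.4 ± 1.16 CPM, RRM2B by 1.91 and DDB2 by 1.82. Among metallothionein genes, whose proteins bind zinc and copper, MT1G was at 36.2 ± 19.3 CPM against 0 counts, at least 241-fold higher, MT1H against 1 count had a ratio with an interval of 85.2 to 18900 and MT1E against 3 counts one of 53.9 to 773. Naive pluripotency genes had 3 higher, 5 when adjusted over the list alone, with a median of 1.67 (adjusted p = 0.0111, adjusted p = 0.785 with an estimated correlation). Cholesterol genes had 13 lower and 2 higher, 13 and 3 when adjusted over the list alone, with a median of -0.57 (adjusted p = 0.00604, adjusted p = 0.895 with an estimated correlation), and NSDHL fell by 1.15. Histones had 7 lower, 8 when adjusted over the list alone, with a median of -1.62 (adjusted p = 0.000248, adjusted p = 0.785 with an estimated correlation). Immediate early genes had 9 lower and 1 higher, 10 and 1 when adjusted over the list alone, with a median of -0.56 (adjusted p = 0.0341, adjusted p = 0.895 with an estimated correlation). PEG3, ZNF280B and LINC02693, at 0 counts in IGF2BP1-rAPOBEC1, were at 0 here too, at least 192-fold, 165-fold and 127-fold lower than in IGF2BP3-hAPOBEC1, and SIX6, an eye field factor, fell by 7.14. Across 14691 genes the effect of rAPOBEC1 against hAPOBEC1 correlated at 0.573 between IGF2BP1 and IGF2BP3 fusions, 0.175 between IGF2BP1 and IGF2BP2 and 0.189 between IGF2BP2 and IGF2BP3. IGF2BP1 and IGF2BP3 had 637 genes higher in both, where independent lists give 205.5, 660 lower in both against 224.9, and 80 opposite. The count was 2646 and 1895 without IGF2BP3-hAPOBEC1 replicates 1 and 2 and 2730 without IGF2BP3-rAPOBEC1 replicate 1, and 23 of 26 named calls stood whichever library was left out, as did 23 of 26 with IGF2BP2.

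**Figure D4:**
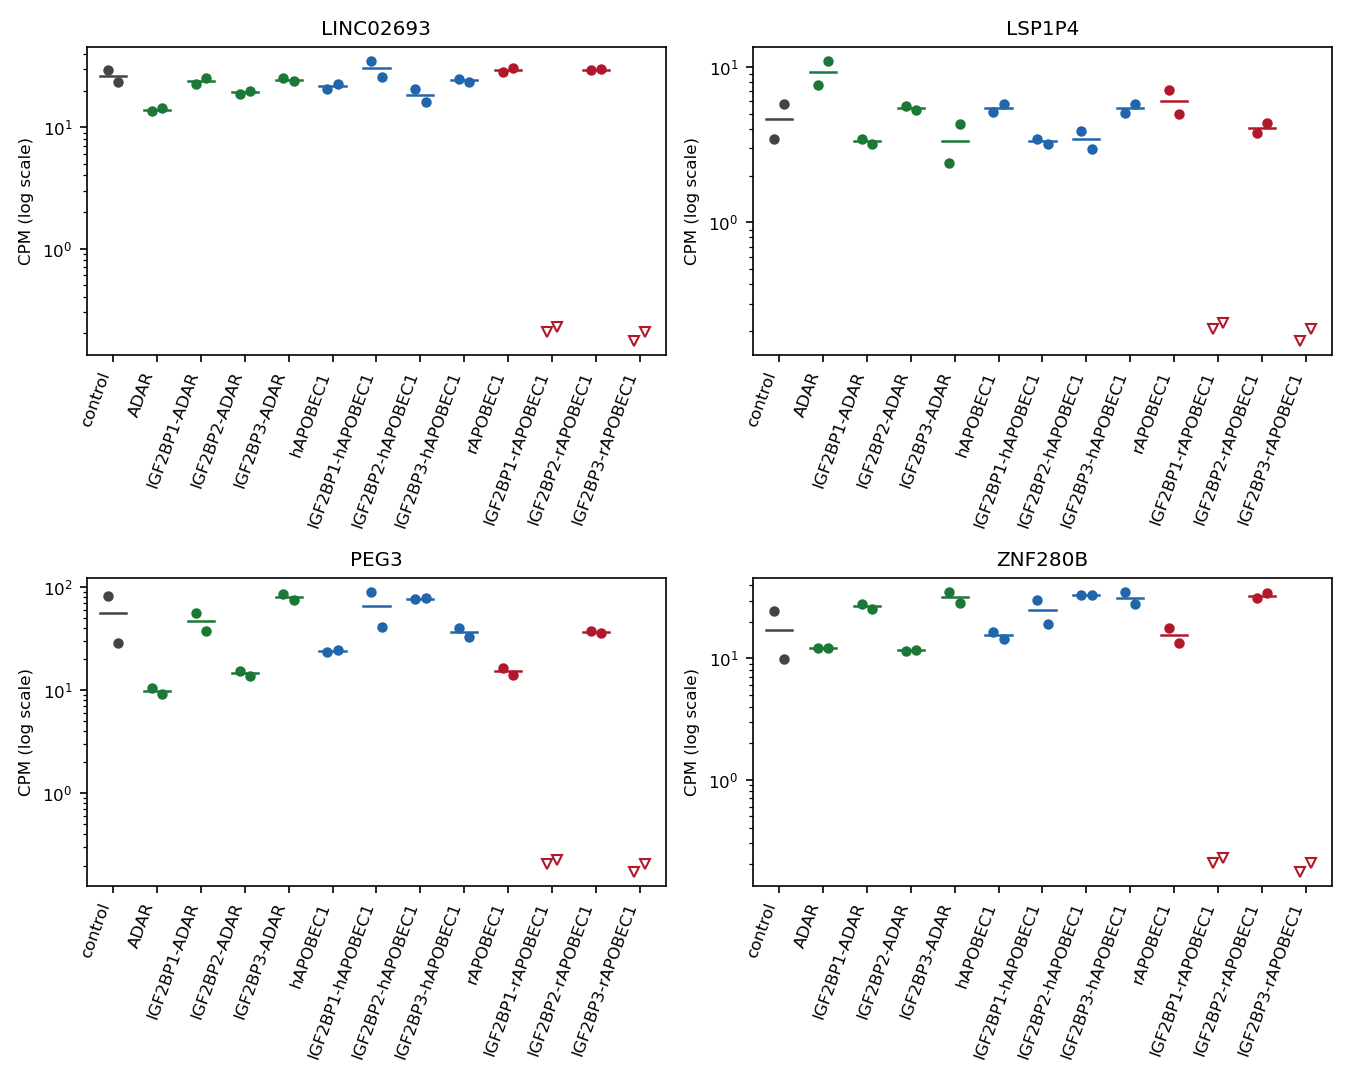
LINC02693, LSP1P4, PEG3 and ZNF280B in CPM on a log axis for the 13 groups, with dots for libraries, bars for group means and open triangles for libraries at 0 counts drawn at their floor of 3 counts. All 4 genes were at 0 in the IGF2BP1-rAPOBEC1 and IGF2BP3-rAPOBEC1 libraries, while PEG3 was at 36.6 CPM in IGF2BP2-rAPOBEC1.

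IGF2BP3-ADAR stood above the mean of both IGF2BP3-APOBEC1 fusions (n = 4) in genes of the neural lineage. Of 16 neural and ectoderm genes 11 were called higher and 1 lower, 13 and 2 when adjusted over the list alone, with a median of 3.50, or 2.63 with bounds (adjusted p = 4.46e-07, adjusted p = 0.785 with an estimated correlation). OTX2, a forebrain factor, rose by 3.40 to 32.8 ± 7.75 from 3.39 ± 2.94 CPM and MAP2, a dendrite protein, by 1.98. DLK1 stood at 15.6 ± 16.2 against 0.976 ± 0.123 CPM. SIX3 was at 5.50 ± 6.23 CPM against 3 counts, a ratio with an interval of 45.4 to 658. PEG3 was at 85.4 and 74 CPM in the libraries of IGF2BP3-ADAR, 40.3 and 32.8 in those of IGF2BP3-hAPOBEC1 and 0 counts in IGF2BP3-rAPOBEC1. TRPC4 rose by 3.94 and the BMP antagonist gene GREM1 by 4.22. TRDN, triadin, fell by 3.51, TBX15 fell by 3.83 and LCP1 fell by 3.19. Immediate early genes had 5 lower and 1 higher, 8 and 2 when adjusted over the list alone, with a median of -0.44 (adjusted p = 0.0234, adjusted p = 0.869 with an estimated correlation), JUN falling by 1.37 while IER3 rose by 0.93. The list lost its call without IGF2BP3-ADAR replicate 2 or IGF2BP3-rAPOBEC1 replicate 2. The 15 heat shock genes had 2 lower, 4 when adjusted over the list alone, with a median of -0.20 (adjusted p = 0.0266, adjusted p = 0.819 with an estimated correlation), a call lost without IGF2BP3-ADAR replicate 2 (adjusted p = 0.525) or IGF2BP3-rAPOBEC1 replicate 1 (adjusted p = 0.062). The 1235 genes called, 700 higher and 535 lower, became 464 when the groups were fitted alone. The count was 2083 and 2609 without IGF2BP3-ADAR replicates 1 and 2, 774 and 778 without IGF2BP2-rAPOBEC1 replicates 1 and 2 and 725 and 414 without IGF2BP3-hAPOBEC1 replicates 1 and 2, and 17 of 18 named calls stood in every case.

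Lists of 2 kinds were not called in any of the 16 planned comparisons. Blood and endothelium markers had 6 genes tested in sets 1 and 3 and 7 in set 2, with a smallest adjusted p of 0.422. The mRNAs that the literature names as IGF2BP targets had 27 and 26 tested and a smallest adjusted p of 0.129, in IGF2BP1-rAPOBEC1 against its control, where 4 were called higher and 8 lower, 6 and 12 when adjusted over the list alone. Over the 16 planned and 2 added comparisons 94 list calls were made at the preset correlation of 0.01 and 0 with an estimated correlation. Of these calls 2 were for editing enzymes, a list that holds the transgene APOBEC1, and are not used here.

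Sets 2 and 4 have no control library, so their lines can be set against the control only across sets, where the set and the line cannot be told apart. On 17252 genes the numbers called were 1182 for IGF2BP2-hAPOBEC1, 2287 for IGF2BP2-rAPOBEC1, 154 for IGF2BP3-ADAR, 2438 for IGF2BP3-hAPOBEC1, 2841 for IGF2BP3-rAPOBEC1 and 1077 for rAPOBEC1 alone. Of the transgenes IGF2BP2 rose by 5.40 in IGF2BP2-rAPOBEC1 and 3.22 in IGF2BP2-hAPOBEC1, and IGF2BP3 by 4.15 in IGF2BP3-hAPOBEC1 and 2.06 in IGF2BP3-rAPOBEC1. Genes that no transgene explains were called too, IGF2BP2 higher by 0.72 in rAPOBEC1 cells (adjusted p = 0.0257) and ADAR lower by 0.59 in IGF2BP2-rAPOBEC1 and 0.60 in IGF2BP3-rAPOBEC1 (adjusted p = 0.0263 and adjusted p = 0.0217). The control libraries of sets 3 and 1 differed in 2300 genes, 13.7% of those tested, with 862 higher and 1438 lower in set 3, in cells that carry no transgene by their label. That is 1 library against 1, with the spread taken from the replicates of other groups, which the labels do not show to be separate cultures. POU5F1, the central pluripotency gene, taken to be counted over 7 sequences in set 1, was at 11790 CPM in the set 1 control and 1528 in the set 3 control.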

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

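The tests of the genes at 0, of the replicate spread and of the splits were chosen after the results were seen, while the differences between groups were planned tests. The effect of rAPOBEC1 against hAPOBEC1 differed between IGF2BP3 and IGF2BP2 fusions, by the interaction term of edgeR, in 3490 genes. The largest positive differences on the log2 scale among named genes were in MT1G (15.86), FAR2P1 (11.36), LINC00664 (10.16), LINC01108 (10.10), MIR205HG (8.94) and MT1X (7.92). The largest negative ones were in SIX6 (-13.04), LINC02693 (-12.49), ZNF280B (-12.15), PEG3 (-11.31), ZNF726 (-9.78) and HMX3 (-9.22). Fitted values of genes at 0 counts in a group depend on the prior count and are no bound.

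The effects of IGF2BP1-ADAR and of ADAR, each against its own control library, differed in 38 genes. Named genes with a higher effect in the fusion were ECEL1P2 (5.10), GRPR (3.54), SORBS2 (3.51), GADD45G (3.46), CHCHD2 (3.07) and SYN3 (3.00). Those with a lower effect were CCDC144NL-AS1 (-3.58), LINC01108 (-3.37), GDF3 (-3.34), LRRN2 (-2.82), MAPRE1 (-2.52) and CSRP1 (-2.38). The effects of IGF2BP1-hAPOBEC1 and of hAPOBEC1 differed in 9 genes: FIGNL2 (2.75), ARMCX6 (-3.43), LINC01356 (-3.20), TRDN (-3.14), SLC39A8 (-3.06), NR5A2 (-2.97), GDF3 (-2.83), and, named after their values were seen, ZNF717 (6.41) and PPIAP46 (-7.09). Without IGF2BP1-hAPOBEC1 replicates 1 and 2 these 9 genes became 2336 and 119, and the 38 became 1169 and 1204. They were 0 without IGF2BP1-ADAR replicate 1 or 2 or ADAR replicate 2 for the 38 (1998, 2050 and 1633 at an unadjusted p under 0.05 by edgeR, 327 by DESeq2's Wald test with all libraries), and 2 without ADAR replicate 1. For the 9 genes the count was 0 without either library of IGF2BP2-ADAR (1172 and 1171 at an unadjusted p under 0.05 by edgeR, 48 higher and 56 lower by DESeq2's Wald test with all libraries) or of hAPOBEC1 (1055 and 1047), and 4 without either ADAR library.

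LINC02693 (chromosome 17, 21428263 to 21574517), LSP1P4 (chromosome 2, 91587019 to 91660038), PEG3 (chromosome 19, 56810077 to 56840728) and ZNF280B (chromosome 22, 22484421 to 22508742) were at 0 counts in the 4 libraries of IGF2BP1-rAPOBEC1 and IGF2BP3-rAPOBEC1. Libraries of 1 line under both labels are excluded, since IGF2BP3 stood at 723.2 CPM or more in IGF2BP3-rAPOBEC1 and at 200.4 or less in IGF2BP1-rAPOBEC1. Silencing was not seen in the IGF2BP2-rAPOBEC1 and rAPOBEC1 libraries, where the lowest value of these genes was 3.77 CPM against a floor of 0.225. A partial effect of the rat enzyme stays open, and its transgene cannot be read in rAPOBEC1 cells. A state shared by the cells of both lines, such as a common parent culture, may explain the pattern, since the effect of rAPOBEC1 against hAPOBEC1 correlated across genes at 0.573 between these fusions and at 0.175 and 0.189 between the other pairs. An effect of these fusions themselves predicts the same correlation and stays open, untested, with 1 group per fusion.

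The IGF2BP1-hAPOBEC1 replicates lay farther apart than those of the other 11 pairs tested (chi-square per degree of freedom 81.25 against 42.87 at most), and replicate 2 correlated less with the control across genes (0.957) than replicate 1 (0.980). More transgene in replicate 2 is excluded, since its APOBEC1 level was 50.2 CPM against 189.4. Cells of the IGF2BP1-rAPOBEC1 line in replicate 2 are excluded as the cause, since 15 genes seen in that line and nearly absent from the other libraries of set 1, replicate 2 aside, allow a share of 7.16% (upper limit 8.59%), while the shift over 1616 genes would need 43%. Handling shared by libraries of the same number stays open, since the replicate difference correlated at 0.315 with that of IGF2BP1-ADAR and at -0.053 with that of IGF2BP1-rAPOBEC1. No biological explanation was tested.

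Splits of the 8 APOBEC1 fusion libraries of set 2 were counted with a model of the split alone, in all 35 splits of 4 against 4. For rAPOBEC1 against hAPOBEC1 1 of 35 gave as many genes, the real one with 2867 against 500 in the highest other. Only 3 of the 35 keep replicates together and the other 32 gave 0 genes, so the count does not exclude a chance difference between lines. For IGF2BP3 against IGF2BP2 3 of 35 gave as many as the real 3 genes, and for the interaction 2 of 35 gave as many as the real 500, with 2867 in the highest other for both, so chance cannot be excluded by this count. The split with 2867 genes is the enzyme split itself, so it points to a structure of the samples, and the model with all groups, which takes the enzyme into account, called 1231 and 3490.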

How the results depend on the processing

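Leaving out the IGF2BP1-hAPOBEC1 pair and the enzyme contrasts within IGF2BP2 and IGF2BP3 were chosen after seeing the data, the other alternatives before. Counts not given here stayed within 1.5 times the reported count. Where a count moved, the cause was not tested. A library left out leaves fewer samples, but that cannot account for rises. Counts of the other lines rose without either IGF2BP1-hAPOBEC1 library, whose pair lay farthest apart and enters the shared spread.

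For lines against their control the counts with no filter were 903 in IGF2BP1-ADAR, 997 in IGF2BP1-hAPOBEC1, 1398 in ADAR, 613 in hAPOBEC1 and 728 in IGF2BP2-ADAR. DESeq2's Wald test gave 341, 303, 1086, 356 and 442 for the same lines. Fitted in their own set, IGF2BP1-ADAR and IGF2BP1-hAPOBEC1 had 0 by edgeR (1095 and 1111 at an unadjusted p under 0.05), IGF2BP1-rAPOBEC1 564, ADAR 4931, hAPOBEC1 3557 and IGF2BP2-ADAR 3392. With no set term the counts were 9, 14, 2116, 948, 627 and 160 in that order. Without the IGF2BP1-hAPOBEC1 pair they were 1538 in IGF2BP1-ADAR, 6680 in IGF2BP1-rAPOBEC1, 2493 in ADAR, 1025 in hAPOBEC1 and 1143 in IGF2BP2-ADAR. Replicates as a block gave 17 in IGF2BP1-ADAR, and the spread of all 26 libraries 73 there and 767 in ADAR. With 1 library left out the counts ran from 1 to 1543 in IGF2BP1-ADAR, 7 to 4399 in IGF2BP1-hAPOBEC1, 2095 to 6703 in IGF2BP1-rAPOBEC1, 16 to 2488 in ADAR, 0 to 1014 in hAPOBEC1 and 1 to 1150 in IGF2BP2-ADAR.

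IGF2BP2-ADAR against ADAR had 87 genes with no filter, 24 by DESeq2, 862 in its own set and 47 without the pair, and moved both ways with 1 library left out. IGF2BP1-ADAR against ADAR had 671 with no filter, 13 with the block, 327 by DESeq2, 1072 with its groups alone, 2323 with no set term, 1175 without the pair and 0 to 1204 with 1 library left out. IGF2BP1-hAPOBEC1 against hAPOBEC1 had 387 with no filter, 1.0e+02 by DESeq2 (48 higher and 56 lower), 0 with its groups alone (563 at an unadjusted p under 0.05 by edgeR), 3339 with no set term and 0 to 2336 with 1 library left out. IGF2BP1-ADAR against the APOBEC1 fusions had 1544 with no filter, 1104 by DESeq2, 18 in its own set, 100 with no set term and 95 to 3637 with 1 library left out. IGF2BP1-rAPOBEC1 against IGF2BP1-hAPOBEC1 had 609 in its own set, 1379 with no set term and 1254 to 6391 with 1 library left out. hAPOBEC1 against ADAR had 2707 with no filter, 7055 in its own set, 114 with no set term, 4702 without the pair and 24 to 4652 with 1 library left out.

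In set 2, groups fitted alone gave 3016 for IGF2BP3 against IGF2BP2, 5473 for the interaction, 464 for IGF2BP3-ADAR against the APOBEC1 fusions and 9047 for the enzyme within IGF2BP2. DESeq2's Wald test gave 1919 for IGF2BP3 against IGF2BP2. With 1 library left out the counts ran from 3970 to 8180 for rAPOBEC1 against hAPOBEC1, 268 to 2985 for IGF2BP3 against IGF2BP2, 1617 to 5469 for the interaction, 414 to 2609 for IGF2BP3-ADAR, 1621 to 7108 for the enzyme within IGF2BP2 and 1895 to 7124 within IGF2BP3.

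Directions turned in 7 cases. With no set term RPL26 was at -1.16 in ADAR (adjusted p = 0.4, and 1.47 to 1.62 with 1 library left out) and -1.32 in IGF2BP2-ADAR (adjusted p = 0.378, and 1.39 to 1.45). With no set term cholesterol genes turned in IGF2BP1-hAPOBEC1 against control (adjusted p = 0.635, range with 1 library left out 0.000219 to 0.0371), hAPOBEC1 against control (0.673, range 0.00409 to 0.0446) and IGF2BP1-hAPOBEC1 against hAPOBEC1 (0.561, range 1.73e-08 to 4.19e-05). Glycolysis genes turned in IGF2BP1-ADAR against ADAR (0.0478, range 0.00517 to 0.156). The p53 targets turned in IGF2BP1-hAPOBEC1 against control without IGF2BP1-hAPOBEC1 replicate 1 (0.835, range 3.1e-12 to 0.835).

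Over all alternatives 5533 of the named fold changes kept direction and call, 862 kept direction alone and 2 turned, and for list tests the numbers were 1548, 237 and 5. Of 339 named calls 190 stood whichever library was left out, and of 94 list calls 56. No list call held with an estimated correlation. In simulated counts for IGF2BP1-ADAR against control 21 of 100 genes with a log2 change of 1 were recovered by edgeR, with 10 false calls, and 38 by DESeq2, with 35 false calls.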

Other observations

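The contrasts within IGF2BP2 and within IGF2BP3 and the tests of the control libraries were chosen after the results were seen. In IGF2BP3 fusions glycolysis and hypoxia genes were higher with rAPOBEC1 than with hAPOBEC1, with 12 of 30 called higher and 1 lower, 15 and 2 when adjusted over the list alone, and a median log2 fold change of 0.96 (camera adjusted p = 0.00671, adjusted p = 0.895 with an estimated correlation, and adjusted p = 0.157 without IGF2BP3-rAPOBEC1 replicate 2). SLC2A3, a glucose carrier, rose by 0.84. Pluripotency genes there had 9 of 26 called higher and 1 lower, 11 and 1 when adjusted over the list alone, and a median of 0.49 (adjusted p = 0.02, adjusted p = 0.895 with an estimated correlation), a call lost without IGF2BP3-hAPOBEC1 replicate 2 (adjusted p = 0.0546) or IGF2BP3-rAPOBEC1 replicate 2 (adjusted p = 0.223). In IGF2BP2 fusions 5 of 8 trophoblast and amnion genes were called higher with rAPOBEC1, also 5 when adjusted over the list alone, with a median of 1.91 (adjusted p = 0.02, adjusted p = 0.785 with an estimated correlation).

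The control libraries of sets 3 and 1, 1 against 1 with the spread of other groups, differed in 2300 genes. Genes that set 2 counts over alternative sequences of the assembly, as set 1 is taken to, had a median log2 difference of -1.16 (717 genes), and the 16056 others one of 0.015. TUBB was at 27050 CPM in the set 1 control and 2256 in the set 3 control. Counting over alternative sequences is consistent with the shift of these genes. Whether it is the only cause stays open, since the 12.1% of the other genes that were called rest on the spread of other groups. Culture, day and library batch cannot be told apart here, with 1 control library per set.

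Of 16 pairs of groups within a set, 5 had a correlation of replicate differences above 0.1. They were the 3 pairs of IGF2BP3 lines (0.124, 0.116 and 0.157), IGF2BP2-hAPOBEC1 with IGF2BP3-ADAR (0.124) and IGF2BP1-ADAR with IGF2BP1-hAPOBEC1 (0.315). The others ran from -0.086 to 0.07 across genes, which are not independent replicates.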
